A study of Mus musculus with 4 samples.

How the data were processed

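RNA was measured in whole mouse embryos of 2 genotypes, wild type and Tc/Tc, at 2 stages, which gave 4 groups with 1 library each. Per the labels' protocols, total RNA was taken with TRIzol LS and strand-specific libraries were made with the ScriptSeq v2 kit. The labels give (C3H/HeH x 101/H)F1 as the mouse strain of origin. The labels give the earlier stage as E7.5 to 8.0 and the later one as E10.0 to 10.5; they are called E8 and E10 here. The number of embryos in each library is not given in the sources used here. Per the submitters' processing notes, Bowtie2, Cuffdiff and the mouse build mm9 were used; versions and the gene annotation are not given in the sources used here.

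The authors deposited 4 pairwise tables of 36808 genes each: wild type E10 against wild type E8, Tc/Tc against wild type at E8, Tc/Tc against wild type at E10, and Tc/Tc E10 against Tc/Tc E8. Per the file headers, each holds FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments) of 2 libraries, the natural log of their fold change and a p-value for each gene. The headers name no adjusted p-value, no mark of which genes were tested and no call of significance. Cuffdiff estimates abundances jointly for the libraries of 1 run, so the same library can have different values in 2 tables. Values of this kind depend on the other RNA in a library: a very abundant transcript lowers the rest.

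The Tc/Tc stage table has a column headed as wild type E10 although the table is named for the Tc/Tc stages. This 1 column was left unused. The fold changes that the authors deposited in that table equal the ratio of the Tc/Tc E10 value in the E10 genotype table to the Tc/Tc E8 value, within 0.01 on the natural log scale, for 89.3% of 11771 genes, against 2.7% with wild type E10 in its place. The Tc/Tc stage comparison therefore used Tc/Tc E10 from the E10 genotype table and Tc/Tc E8 from the stage table. It joins values estimated in separate tables.

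The technical error was read from libraries that occur in 2 tables. Over genes at 1 FPKM or more in both, the SD of the log2 difference was 0.061 for wild type E8 (12935 genes), 0.174 for Tc/Tc E8 (12638 genes) and 0.174 for wild type E10 (13294 genes). The size rule below was passed between 2 estimates of 1 library by 9, 64 and 70 genes. This covers re-estimation only, not the spread between embryos or library preparations, which cannot be had from 1 library per group. The shifts of Tc/Tc E8 and of wild type E10 between their 2 estimates correlated across 11735 genes with r = 0.71. With the estimates used, they move the same genes the same way in both genotype comparisons, and likewise in both stage comparisons. Depth is unknown, so no counting interval was computed.

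In the 3 tables where both columns were used, a p-value of 1 and a value of 0 in both libraries coincided in all 36808 genes. Such a pair can be a failed estimate, since genes used by every cell were among them. Rpl13a, a ribosomal protein gene, was listed at 0 in each column used, and Eif4a2, a translation factor gene, was listed at 0 in the wild-type stage table and at 329 FPKM for wild type E8 in another table. Genes at 0 in both libraries of a table were therefore left out of that comparison, a gene at 0 is only said to be listed at 0, and no fold is given against 0. For the Tc/Tc stage pair a gene was also left out when either table had no estimate, unless the deposited fold change showed that Tc/Tc E10 was at 0.

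Gene symbols and Ensembl identifiers are those in the files. In 25 genes the symbol had been turned into a date, and all 25 were named by identifier from a GENCODE M21 name table, which held 31838 of the 36808 identifiers. Symbols on more than 1 gene, 143 of them, were not named or used in lists. The files give no coordinates and the annotation at hand is of another build than mm9, so no coordinates are given.

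Ratios were computed as log2 of (FPKM + 1) over (FPKM + 1), which understates the ratio of low genes, among genes with at least 1 FPKM in 1 or both libraries. A gene passed the size rule at an absolute log2 ratio of 1 or more, a fold of 2. The rule is a description of single libraries: there is no replicate check and no test of the genotypes or stages. Ratios are Tc/Tc over wild type or E10 over E8. The 2 genotype comparisons share no library, nor do the 2 stage comparisons; for those pairs the number of shared genes is set beside n1 × n2 / N. A stage and a genotype comparison always share a library and were not correlated with each other. Only the mean of both stage ratios was set against the genotype ratios, in the last part.

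Lists of genes, 34 with 381 genes in all, were fixed before the data were examined, together with the comparisons, the size rule, the naming rule and most alternatives. They are primitive streak and nascent mesoderm, presomitic mesoderm and tail bud, node and notochord, hedgehog response and ventral neural tube, somite, skeletal muscle, cartilage, Hox genes in 3 ranges of paralog groups, heart, neural progenitor and brain patterning, neuron, neural crest, limb bud, intermediate mesoderm and kidney, gut endoderm, left-right and Nodal pathway, epiblast and germ cell, Wnt feedback targets, BMP response, epithelial, mesenchymal, endothelium, erythroid, visceral endoderm and yolk sac, trophoblast, decidua and uterine natural killer cell, macrophage, p53 response, hypoxia and glycolysis, immediate early and heat shock, sex-linked, and common reference genes. Of the 381 genes, 378 were in the tables, and 7 stood on more than 1 list. For a list with at least 3 measured members, the median log2 ratio is given with its percentile among 10000 random lists of the same size, drawn from 20 bins of mean log2 expression. A percentile describes these libraries and is not a p-value.

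Named genes are T in each library; among genes with 5 FPKM or more in the higher library, the 8 highest and 8 lowest log2 ratios of each genotype comparison and the 6 highest and 6 lowest of each stage comparison; up to 4 members of each list with the largest absolute ratios; and, among genes past the size rule in both genotype comparisons, the 5 in each direction whose smaller ratio was largest. Predicted or unnamed genes, small RNAs, ribosomal RNAs, histone, ribosomal protein and mitochondrial genes were left out of naming. List members named outside that rule are marked in the text.

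Alternatives were other pseudocounts, minimums and folds, rescaling to a median ratio of 0 or to equal totals, values of the same libraries from the other tables, and random lists not matched on expression. Added after seeing the data were the deposited p-values with Benjamini-Hochberg adjustment, genes above 0 in both libraries only, and protein-coding genes only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The size rule was tested on data simulated from the E8 genotype comparison (13205 genes, noise SD 0.2 on the log2 scale). The changed genes were drawn from those at 5 FPKM or more, so recovery of lower genes was not tested. The rule recovered 100% of 100 genes changed 4-fold and 3.0% of 100 genes changed 1.5-fold, and passed 3 unchanged genes. Re-estimation of 1 real library passed up to 70 genes, so the 3 understates false passes in these data.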

Results

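Tc is a mutant allele of T (Brachyury), the T-box transcription factor of the primitive streak, tail bud and notochord. Whole embryos, wild type or homozygous (Tc/Tc), were profiled by directional mRNA-seq at E8 and at E10, with 1 library for each of the 4 groups. Total FPKM per library was 629048 for wild type E8, 737448 for Tc/Tc E8, 598365 for wild type E10 and 610808 for Tc/Tc E10, in the genotype tables. Between 12900 and 13583 genes reached 1 FPKM in each. Read depth is unknown and no group has replicates, so the values below carry no SD, and no difference was tested against the spread between embryos. Re-estimation of 1 library in another table gave a log2 SD of up to 0.174.

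T itself (ENSMUSG00000062327) was present in each library. It stood at 36.7 FPKM in wild type and 48.3 in Tc/Tc at E8, a log2 ratio of 0.39, below the size rule. At E10 it stood at 7.18 FPKM in wild type and 30.4 in Tc/Tc, a log2 ratio of 1.94. In wild type T was lower at E10 than at E8 by a log2 ratio of -2.07, and in Tc/Tc by -0.39. Transcript level does not show which allele was read, so it is not a check of genotype. In the tables of the stage comparisons the values of T were 36.8 and 7.99 FPKM in wild type at E8 and E10, and 40.0 in Tc/Tc at E8.

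**Figure D1:**
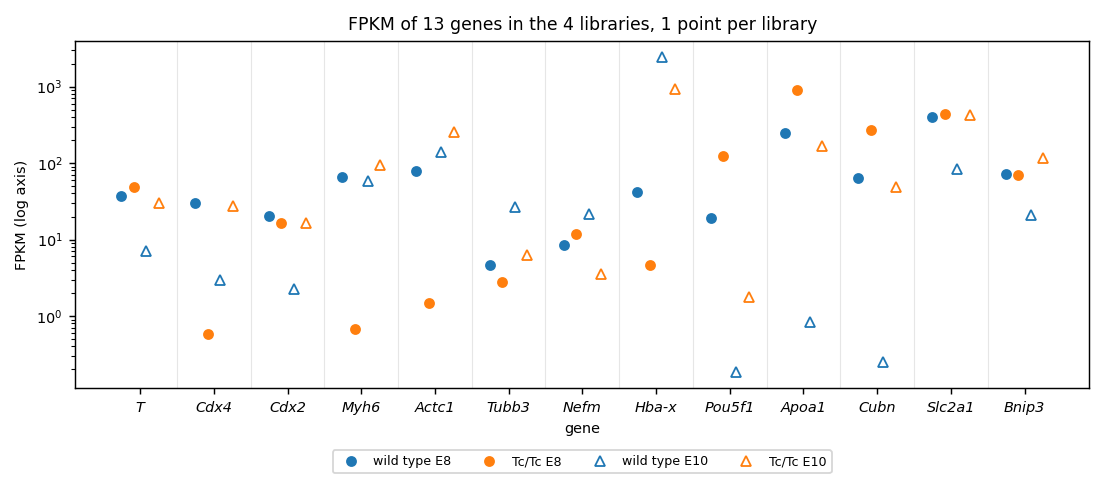
FPKM on a log axis for 13 genes, with 1 point per library: filled circles are E8 and open triangles E10, blue is wild type and orange Tc/Tc, from the 2 genotype tables. At E10 the Tc/Tc points of T (30.4), Cdx4 (27.1) and Apoa1 (165) lie above those of wild type (7.18, 2.99 and 0.827), while at E8 Myh6 is at 0.686 in Tc/Tc and 65.3 in wild type.

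The first genotype comparison asked which transcripts differ in Tc/Tc embryos at E8, when T is active in the streak and early notochord. Lower in the Tc/Tc library were 11 of 14 heart genes, 11 of 19 presomitic mesoderm and tail bud genes and 6 of 7 genes of Hox groups 5 to 8. Higher were 13 of 14 genes of the visceral endoderm and yolk sac, 5 of 9 of the epiblast and 5 of 11 of the p53 response. Of 13547 genes, 571 were higher and 407 lower by the size rule, with a median log2 ratio of 0.055 over all genes. Rescaled to equal totals the split was 368 higher and 546 lower, and with values of the same libraries from the other tables it was 358 higher and 419 lower.

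Heart genes had the lowest median of all lists at E8. Of 14 measured members, 11 were lower, 1 higher and 2 within the rule, with a median log2 ratio of -2.06 (percentile 0.0). Myh6 and Myh7, the cardiac myosin heavy chains, stood at 0.686 and 1.29 FPKM in Tc/Tc against 65.3 and 32.4 in wild type. Actc1, cardiac actin, was at 1.47 against 79.1 FPKM, and Myl4, an atrial light chain, at 2.31 against 58.7. The member that was higher was Hand1, named after its value was seen, at 80.9 against 33.6 FPKM; the estimates of Hand1 in the other tables, 67.7 and 33.5, fell just short of the rule. Ankrd1, a cardiac stress protein gene that is on no list, was at 0.468 against 23.1 FPKM, and Nepn at 0.498 against 21.2.

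Among presomitic mesoderm and tail bud genes, 11 of 19 were lower at E8 and 1 was higher, with a median of -1.38 (percentile 0.0). Cdx4, a caudal-type homeobox gene, was at 0.574 FPKM in Tc/Tc and 29.7 in wild type. Msgn1, a regulator of presomitic mesoderm, was listed at 0 in Tc/Tc and stood at 7.90 FPKM in wild type. Dll1, a Notch ligand of the segmentation clock, was at 3.93 against 20.7 FPKM, and Fgf8 at 2.77 against 11.8. The higher member was Wnt8a, at 28.4 against 10.2 FPKM, named after its value was seen. Somite genes were lower in 8 of 10 members, with a median of -1.26 (percentile 0.0). Pax3 was at 0.656 against 6.81 FPKM and Foxc2 at 2.14 against 9.55. Cartilage genes were lower in 4 of 5 (median -1.25, percentile 0.0), among them Col2a1 at 6.21 against 23.3 FPKM (listed at 0 for Tc/Tc in the other table) and Sox9 at 7.94 against 25. The other table gave 4.65 for Sox9 in the same Tc/Tc library, a log2 ratio of -2.20. Of the kidney and intermediate mesoderm genes, 4 of 7 were lower (median -1.02, percentile 0.1), with Osr1 at 0.771 against 8.12 FPKM and Pax8 listed at 0 against 3.25.

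Hox genes were lower at E8 in each range of paralog groups. In groups 1 to 4, 5 of 10 were lower (median -0.97), in groups 5 to 8, 6 of 7 (median -2.0), and in groups 9 to 13, 3 of 5 (median -1.68), each at percentile 0.0. Hoxc8 was at 0.385 FPKM in Tc/Tc and 18.2 in wild type, Hoxb9 at 0.974 and 22.0, and Hoxd3 at 0.0646 and 8.74. Hoxa9 was listed at 0 in Tc/Tc against 8.07 FPKM.

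Streak, node and signalling genes were mixed at E8. In the primitive streak list, 1 of 5 members was higher and 1 lower (median -0.70, percentile 1.2). Eomes was at 4.65 FPKM in Tc/Tc and 0.345 in wild type, and Evx1 at 1.92 and 6.15. With a pseudocount of 5 this percentile was 5.2. In the node and notochord list 1 of 6 was lower (median -0.18, percentile 22.0), and that was Shh, at 0.193 against 3.28 FPKM. Hedgehog response and ventral neural tube genes had a median of -0.54 (percentile 0.8), with 1 of 6 lower, Nkx6-1 at 0.659 against 4.01 FPKM. No Wnt feedback target and no BMP response gene passed the rule. Their medians were -0.23 over 10 genes (percentile 2.4, and 4.6 with a pseudocount of 5) and 0.18 over 9 genes (percentile 78.4). Left-right and Nodal pathway genes had a median of -0.99 over 3 genes (percentile 0.7), with 1 lower, the Nodal co-receptor gene Tdgf1 at 0.248 against 2.56 FPKM.

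The lists of ectodermal derivatives, limb and vessel genes had negative medians at E8, with most members of each within the size rule. Neural progenitor and brain patterning genes were lower in 4 of 9 (median -0.67, percentile 0.0), led by En1 at 0.346 against 6.59 FPKM and Egr2 at 0.161 against 3.37. Neuronal genes were lower in 2 of 8 (median -0.44, percentile 1.7), Mnx1 and Pou4f1; with a minimum of 5 FPKM the percentile was 23.5. Neural crest genes were lower in 2 of 6 (median -0.55, percentile 2.1, and 4.5 with a pseudocount of 0.1), Foxd3 and Sox10, both listed at 0 in Tc/Tc. Limb bud genes were lower in 3 of 8 (median -0.51, percentile 0.4), with Tbx4 at 0.214 against 6.65 FPKM. Endothelial genes were lower in 2 of 11 (median -0.52, percentile 0.1), Cdh5 and Emcn, and Emcn was listed at 0 in Tc/Tc. Mesenchymal genes were lower in 3 of 10 (median -0.84, percentile 0.0), among them Cdh2 at 13.5 against 48.9 FPKM and Twist1 at 6.36 against 19.2. The single measured skeletal muscle gene, Mylpf, had a log2 ratio of -0.06. Erythroid genes went both ways, with 1 of 10 higher and 3 lower and a median of 0.15 (percentile 80.5). The embryonic globin Hba-x was at 4.58 against 41.7 FPKM, and the erythroid factor Gata1 at 7.29 against 0.782.

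Visceral endoderm and yolk sac genes were higher at E8 in 13 of 14 members, with a median of 1.63 (percentile 100). Trf, transferrin, was at 132 FPKM in Tc/Tc and 20.1 in wild type, although the other table gave 65.5 for the same Tc/Tc library. The endocytic receptor Cubn was at 270 and 63.4, and the apolipoprotein Apoa1 at 905 and 247. Trophoblast genes were higher in 3 of 4 (median 1.17, percentile 99.8), with Elf5 at 9.90 against 0.425 FPKM; with values from the other tables Esx1 fell below the rule (0.95 from 1.07). Gut endoderm genes were higher in 2 of 7 (median 0.46, percentile 98.6), Trh and Foxa3, which were at 13.3 and 3.27 FPKM against 4.42 and 0.943. Epithelial genes were higher in 2 of 10 (median 0.61, percentile 100), with Cdh1, E-cadherin, at 85.1 against 25 FPKM. Of decidual genes only Prl8a2 was measured, at 3.21 FPKM in Tc/Tc and listed at 0 in wild type, and of 3 macrophage genes 1, Fcgr3, was higher (median -0.07, percentile 48.1).

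Epiblast and germ cell genes were higher in 5 of 9 at E8 and lower in 1, with a median of 1.21 (percentile 100). The pluripotency factor Pou5f1 was at 125 FPKM in Tc/Tc and 18.9 in wild type, and L1td1 at 44.3 and 9.60. Among p53 response genes 5 of 11 were higher and 0 lower (median 0.72, percentile 100). Ccng1 was at 78.9 against 19.2 FPKM, Phlda3 at 7.66 against 1.27, Eda2r at 4.61 against 0.819, and the cell cycle inhibitor Cdkn1a at 12.3 against 3.40. Among the genes open to naming, the highest ratios were those of Fabp3, a fatty acid binding protein gene (16.1 against 1.20 FPKM), and the metallothionein Mt2 (162 against 20.1 FPKM). Cd82 (22.5 against 3.40), Fabp1 (11.6 against 1.44) and Dnase2a (5.41 against 0.247) were also among the highest of these; Dnase2a was listed at 0 for both libraries in the other tables.

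Immediate early and heat shock genes were lower in 4 of 11 at E8 (median -0.40, percentile 0.2). Egr1 was at 6.98 FPKM in Tc/Tc and 27.6 in wild type, and Fos at 12.3 and 35.8. Hypoxia and glycolysis genes had a median of 0.07 over 13 genes (percentile 39.6), and none passed the rule. Common reference genes had a median of 0.25 over 9 genes (percentile 86.5), with Ywhaz the farthest at a log2 ratio of 0.94. Sex-linked genes had a median of 0.13 over 4 genes (percentile 61.4). The Y-linked gene Eif2s3y was at 116 FPKM in Tc/Tc and 81.0 in wild type, and Xist at 0.576 and 0.193, so both E8 libraries held male RNA.

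**Figure D2:**
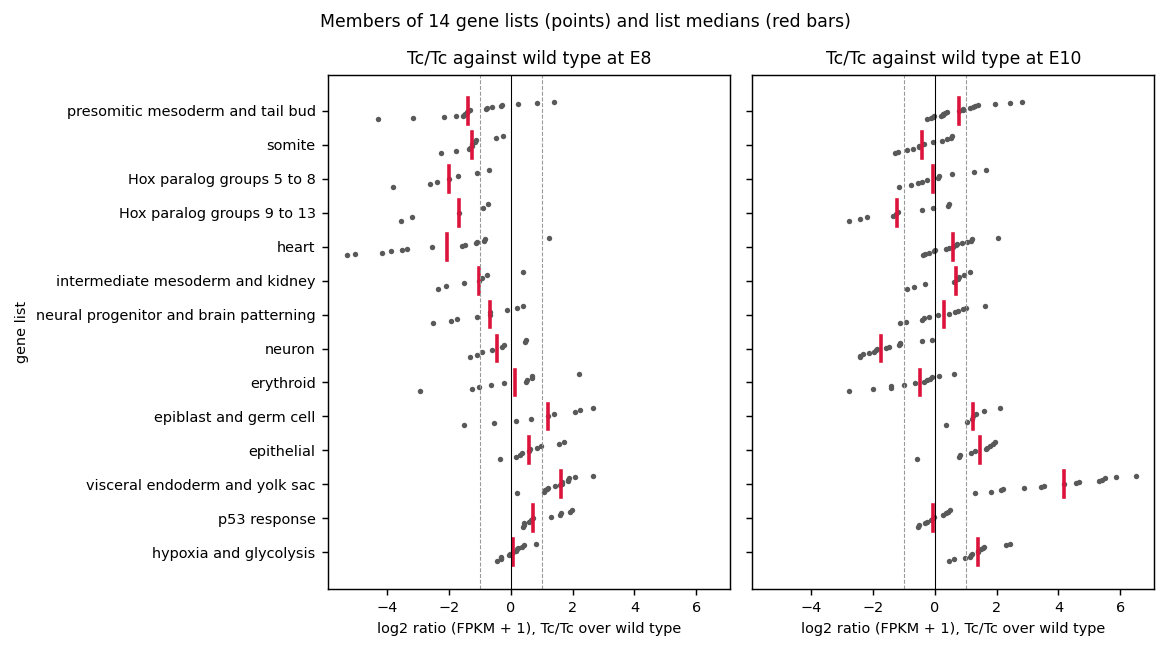
Log2 ratio of FPKM + 1, Tc/Tc over wild type, for the members of 14 gene lists at E8 (left) and E10 (right); each point is a gene, red bars are list medians and dashed lines mark the size rule. Heart genes have a median of -2.06 at E8 and 0.59 at E10, neuronal genes -0.44 and -1.72, and visceral endoderm and yolk sac genes 1.63 and 4.18.

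The E10 comparison asked the same of embryos in which trunk and tail are forming. In the Tc/Tc library, all 15 yolk sac genes, 10 of 13 hypoxia and glycolysis genes, 7 of 10 epithelial genes and 7 of 19 presomitic and tail bud genes were higher. Lower were 12 of 14 neuronal genes, 6 of 10 posterior Hox genes and 5 of 12 erythroid genes. Of 14265 genes, 705 were higher and 440 lower. The median log2 ratio over all genes was 0.161, and with ratios centred on it the split was 487 higher and 568 lower. With the wild-type E10 values of the other table it was 496 higher and 463 lower. No list outside the middle 95% of random lists changed sign when ratios were centred.

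All 15 visceral endoderm and yolk sac genes were higher at E10 (median 4.18, percentile 100). Apoa1 was at 165 FPKM in Tc/Tc and 0.827 in wild type, Apob at 61.3 and 0.370, transthyretin (Ttr) at 130 and 2.10, and Cubn at 48.9 and 0.249. Apoc2 and Spink3 were at 56.9 and 24.2 FPKM in Tc/Tc and listed at 0 in wild type. So were 2 genes on no list, S100g at 107 FPKM in Tc/Tc and the globin-like Hbb-bh0 at 32.7. Epithelial genes were higher in 7 of 10 (median 1.48, percentile 100), with the keratins Krt19 at 29.3 against 6.80 FPKM, Krt18 at 115 against 30.2 and Krt8 at 95.1 against 26.6. Gut endoderm genes were higher in 3 of 7 (median 0.53, percentile 98.3, and 93.9 with a pseudocount of 5), Cldn6, Foxa1 and Hhex, with log2 ratios of 1.66, 1.13 and 1.10. The trophoblast gene Plac1 had a log2 ratio of 0.61, no decidual gene was measured, and the measured macrophage genes, Mrc1 and Cd68, had ratios of 0.80 and -0.18.

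Hypoxia and glycolysis genes were higher at E10 in 10 of 13 (median 1.40, percentile 100). Bnip3, a hypoxia-induced mitophagy receptor, was at 117 FPKM in Tc/Tc and 21.1 in wild type, the glucose transporter Slc2a1 at 422 and 84.4, Ndrg1 at 12.7 and 3.57, and Aldoa at 929 and 316. Common reference genes had a median of 0.24 (percentile 41.7), with 1 of 9 past the rule, Ywhaz, at 670 against 285 FPKM; with the other estimate of wild type, 530 FPKM, its log2 ratio was 0.34. Gapdh, itself glycolytic, was at 405 against 203.

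Presomitic mesoderm and tail bud genes were higher at E10 in 7 of 19 and lower in 0 (median 0.80, percentile 100). The caudal-type genes Cdx4, Cdx2 and Cdx1 were at 27.1, 16.3 and 5.12 FPKM in Tc/Tc and 2.99, 2.22 and 0.576 in wild type, and Msgn1 was at 5.57 and 1.5. Of the primitive streak genes 2 of 4 were higher, Evx1 and Lhx1 (median 0.69), at the upper edge of the middle 95% of random lists. Node and notochord genes were higher in 3 of 7 (median 0.67, percentile 99.3), with Dand5 at 4.87 against 0.867 FPKM and Foxa2 at 8.28 against 3.03. Wnt feedback targets were higher in 2 of 10, Cdx1 and Sp5 (median 0.59, percentile 99.9, and 72.6 with a minimum of 5 FPKM). Left-right and Nodal genes had a median of 0.41 over 3 genes (percentile 88.9), with 1 higher, Tdgf1. No BMP response gene passed the rule (median 0.13, percentile 34.3). Epiblast and germ cell genes were higher in 6 of 7 (median 1.24, percentile 100, and 96.2 with a minimum of 5 FPKM), with Lin28a at 222 against 73.2 FPKM and L1td1 at 6.60 against 0.768.

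Neuronal genes were lower at E10 in 12 of 14 (median -1.72, percentile 0.0). Neurod1 and Neurod4, proneural factors, were listed at 0 in Tc/Tc and stood at 4.33 and 4.30 FPKM in wild type. The neurofilament Nefm was at 3.51 against 21.3 FPKM and Elavl4 at 1.37 against 9.31. Other genes with neural expression were among the lowest ratios open to naming, with Pou3f3 at 0.632 against 11.8 and Fabp7 at 2.60 against 25.1. Syp, synaptophysin, was at 1.18 against 15.1 FPKM, but the other table gave 4.92 for the same wild-type library, a log2 ratio of -1.44. Somatostatin (Sst) was listed at 0 in Tc/Tc against 6.20 FPKM. Neural progenitor and brain patterning genes had a median of 0.29 (percentile 87.2), with 2 of 12 higher, Egr2 and En1, and 1 lower, Hes5. Neural crest genes had a median of 0.51 over 6 genes (percentile 98.0), with none past the rule; with other pseudocounts the percentile was 97.4 and 93.7. In the hedgehog and ventral neural tube list 1 of 8 was lower, the motor neuron progenitor gene Olig2, at 0.781 against 4.34 FPKM (median 0.07, percentile 43.3).

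Posterior Hox genes were lower at E10, with 6 of 10 in groups 9 to 13 past the rule (median -1.23, percentile 0.0). Hoxd11 was at 0.547 FPKM in Tc/Tc and 9.66 in wild type, Hoxd10 at 0.335 and 6.09, Hoxc10 at 1.66 and 11.0, and Hoxd13 at 0.391 and 2.54. Groups 5 to 8 had 2 of 10 higher and 1 lower (median -0.07, percentile 4.5), with Hoxa7 at 37.6 against 11.3 FPKM (listed at 0 for wild type in the other table), Hoxc8 at 26.8 against 10.6 and Hoxc5 at 1.69 against 4.91. In groups 1 to 4, 3 of 10 were higher (median 0.03, percentile 16.5), with Hoxb1 and Hoxd1 at log2 ratios of 1.47 and 1.34.

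**Figure D3:**
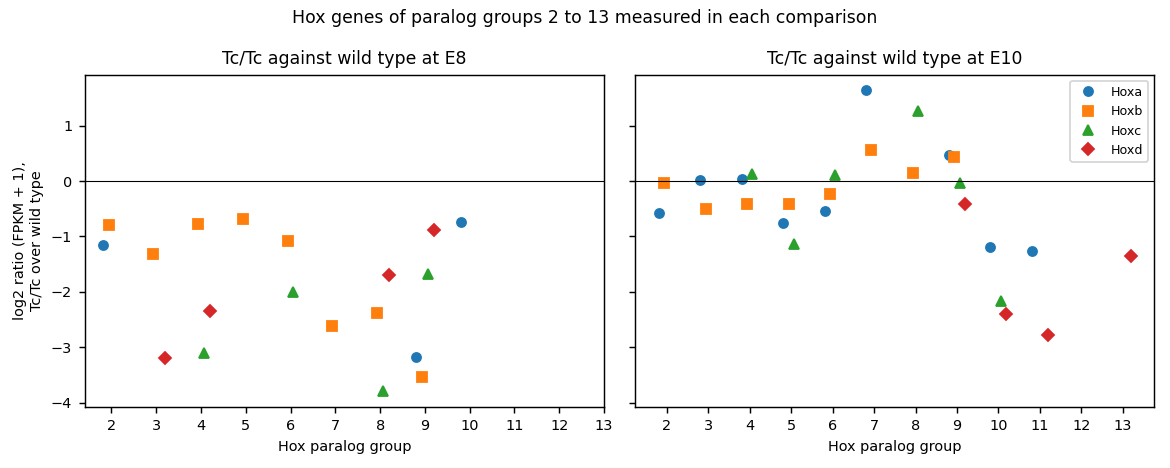
Log2 ratio of FPKM + 1, Tc/Tc over wild type, for measured Hox genes of paralog groups 2 to 13 at E8 (left, 19 genes) and E10 (right, 27 genes); marker shape and colour give the cluster. At E10 Hoxd11 lies at -2.78 and Hoxc10 at -2.17, while Hoxa7 lies at 1.65.

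Heart genes were higher at E10 in 4 of 15 and lower in 0 (median 0.59, percentile 99.9). Hand1 was at 46.7 FPKM in Tc/Tc and 10.6 in wild type, Nkx2-5 at 4.53 and 1.38, Myl7 at 149 and 64.9 and Tnnt2 at 117 and 55.8. Kidney and intermediate mesoderm genes had a median of 0.69 over 8 genes (percentile 99.9, and 97.3 with a minimum of 5 FPKM), with Osr1 higher, at 9.51 against 3.74 FPKM. Somite genes were lower in 2 of 12 (median -0.42, percentile 0.0), Pax1 and Meox2. Cartilage genes had 1 of 7 higher and 1 lower (median -0.30, percentile 0.3), Col9a3 and Col9a1. Col9a3 passed narrowly, at 4.01 against 1.48 FPKM (log2 ratio 1.02), and was listed at 0 for wild type in the other table. Limb bud genes were lower in 3 of 10 (median -0.08, percentile 7.1), with Alx4 and Prrx1 among them. Mesenchymal genes had a median of -0.46 (percentile 0.0), with 1 of 11 lower, Col3a1 at 13.9 against 54.7 FPKM. Skeletal muscle genes had a median of -0.41 over 3 genes (percentile 8.6), with Myog listed at 0 in Tc/Tc against 1.03 FPKM. Barx1 and the noncoding RNA Dnm3os were also among the lowest ratios open to naming, at 0.303 against 7.94 and 0.0777 against 8.53 FPKM. The other table gave 14.1 FPKM for Dnm3os in the same wild-type library, a log2 ratio of -3.81.

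Erythroid genes were lower at E10 in 5 of 12 (median -0.48, percentile 0.0). The embryonic globin Hbb-y was at 250 FPKM in Tc/Tc and 1727 in wild type, and Hba-a2 at 292 and 1158. The globin genes are near-identical in parts, so how reads were shared among them is uncertain. Endothelial genes had a median of 0.30 over 12 genes (percentile 90.7), with Etv2, a regulator of endothelial and blood progenitors, at 7.07 against 0.736 FPKM and Emcn at 5.88 against 15.5. No p53 response gene passed the rule (median -0.04 over 11, percentile 12.6), and no immediate early gene (median 0.11 over 9, percentile 52.6, and 2.1 with a minimum of 5 FPKM). Xist was at 124 FPKM in Tc/Tc and 122 in wild type, while Eif2s3y was listed at 0 in both.

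Across the 12869 genes measured in both genotype comparisons, which share no library, 191 were higher at both stages, where independent lists would share 22.2, and 44 were lower at both, against 6.3. The log2 ratios correlated across genes with r = 0.31, and genes are not independent replicates. Re-estimation shifts of Tc/Tc E8 and wild type E10 correlated across 11735 genes (r = 0.71). They move the same genes the same way in both comparisons, so the 2 lists are not independent in error. How much of the overlap and of r = 0.31 is technical was not determined. Trf, Folr1, L1td1, Cubn and Ctsh were higher at both stages. Folr1, a folate receptor gene, had log2 ratios of 2.18 at E8 and 2.5 at E10, and Ctsh, cathepsin H, 2.03 and 4.20. Lower at both stages were Serpinf1 (-1.66 and -2.16), Postn, a matrix protein gene (-1.65 and -1.74), Col3a1 (-1.54 and -1.90), Hba-x (-2.93 and -1.41) and Zfhx4 (-1.38 and -1.41). In opposite directions, 20 genes were higher at E8 and lower at E10, where independent lists would share 7.8. Another 36 were lower at E8 and higher at E10, against 18.1. Both sets include small RNA and unnamed genes, such as SNORD56.1 (4.16 and -3.90) in the first and SNORA27.1 (-1.93 and 2.30) in the second. The overlap was not computed without them, so it does not show an excess among named protein-coding genes. With values from the other tables, 110 genes were higher at both stages.

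The wild-type stage comparison gives the change between E8 and E10 on the normal background. Of 14239 genes, 1048 were higher and 734 lower at E10; with values from the other tables the split was 739 and 796. The stages also differed in sex-linked genes: 4 were lower at E10, led by Eif2s3y at 81.1 FPKM and then listed at 0, and Xist was higher, at 122 against 0.193 FPKM. Stage and the sex of the embryos therefore cannot be told apart in either stage comparison. Erythroid genes were higher in 10 of 12 (median 3.09, percentile 100), with Hbb-y at 1727 against 1.69 FPKM and the band 3 gene Slc4a1 at 38.5 against 0.0829. Neuronal genes were higher in 11 of 15 (median 1.74, percentile 100), and Hox groups 9 to 13 in 7 of 10 (median 1.29, percentile 100). All 14 measured visceral endoderm and yolk sac genes were lower at E10 (median -4.96, percentile 0.0), among them Apoa1 at 0.979 against 247 FPKM. Presomitic mesoderm genes were lower in 9 of 19 (median -0.96, percentile 0.0), with Cdx1 at 0.576 against 17 FPKM, and epiblast genes in 6 of 7 (median -1.47, percentile 0.0). Hypoxia and glycolysis genes were lower in 3 of 13 (median -0.75, percentile 0.0). Heart genes were higher in 3 of 15 and lower in 1 (median 0.26, percentile 97.9, and 92.5 among lists not matched on expression), with Myl2, a ventricular light chain, at 124 against 14.1 FPKM.

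In Tc/Tc, 1066 of 13845 genes were higher at E10 than at E8 and 564 lower, with a median of 0.124 over all genes; centred on it the split was 839 and 726, and with libraries rescaled to equal totals it was 1478 and 470. Heart genes were higher in 13 of 14 (median 3.14, percentile 100). Actc1 was at 256 FPKM at E10 and 1.47 at E8, and Myh6 at 93.9 and 0.679. Presomitic mesoderm genes were higher in 11 of 19 and lower in 2 (median 1.32, percentile 100), with Cdx4 at 27.1 against 0.574 FPKM and Wnt8a at 1.03 against 28.4. Hox groups 5 to 8 were higher in 5 of 7 (median 2.22, percentile 100). Erythroid genes were higher in 8 of 12 (median 2.48, percentile 100), with Hba-x at 931 against 4.58 FPKM. Neuronal genes were higher in 1 of 8 and lower in 1 (median 0.38, percentile 71.0). Hypoxia and glycolysis genes were higher in 2 of 13 (median 0.57, percentile 100). With the other estimate of Tc/Tc E8 the median was 0.26 (percentile 99.3), and Bnip3, 1 of the 2, fell below the rule (0.76 from 1.15). Visceral endoderm and yolk sac genes were lower in 13 of 15 (median -2.13, percentile 0.0), Pou5f1 was at 1.79 against 125 FPKM, and 4 of 11 p53 response genes were lower, Ccng1 at 15.2 against 76.5 FPKM (median -0.93, percentile 0.0). The stage comparisons share no library. Of 13257 genes measured in both, 354 were higher in both, where independent lists would share 56.2, and 270 were lower in both, against 24.8. The correlated re-estimation shifts of Tc/Tc E8 and wild type E10 act on both, so these lists are not independent in error.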

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

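All tests in this part, with the bounds they use, were chosen after the values had been seen, and those of a lag and of dilution were revised after earlier versions had given results. For a lag, the first version counted 7 of 7 presomitic and 4 of 4 heart genes as lower in wild type at E10 than at E8, and the next counted 6 of 7 and 3 of 4 within 2-fold of wild type E8 in Tc/Tc E10, as were 82.2% of 619 other genes higher at E10. The same versions, which a lag would pass, counted 10 of 10 and 10 of 10 hypoxia and glycolysis genes and 14 of 14 and 13 of 14 visceral endoderm and yolk sac genes. For dilution, the median of presomitic and heart genes at E8 differed from that of neural progenitor genes by -0.73, with a 95% bootstrap interval over genes of -1.60 to 0.51, and 18 of 33 presomitic and heart genes lay within 2-fold of their median; neither decided. Of 36 genes that were lower in Tc/Tc at E8 and higher at E10, the 13 that the naming rule picked are given here. They passed the size rule in opposite directions at the 2 stages. These differences between stages were not tested, since each group has 1 library. The log2 ratio at E10 minus that at E8 was 7.10 for Cdx4, 6.12 for Nepn, 5.59 for Ankrd1, 5.06 for Hoxc8, 4.70 for Myl7 and 4.39 for Tnnt2. It was 3.55 for Egr2, 3.51 for Osr1, 3.51 for En1, 3.0 for Evx1, 2.86 for Tdgf1 and 2.80 for Nkx2-5. At E10 En1 (1.02), Tnnt2 (1.06) and Osr1 (1.15) passed the rule by less than the median over all genes, 0.161. Centred on that median, they would fall below the rule. Egr2 stood at 3.37 FPKM or less and Tdgf1 at 2.56 FPKM or less in the genotype comparisons. Msgn1, the last of the 13, was listed at 0 in Tc/Tc at E8 and is given no difference. Whole lists with opposite medians, each outside the middle 95% of the random lists at both stages as reported, were heart (difference 2.65), presomitic mesoderm and tail bud (2.18), intermediate mesoderm and kidney (1.71), neural crest (1.06) and Wnt feedback targets (0.82). Under other settings 3 of these lists lay inside that middle. Neural crest did so at E8 (percentile 4.5) and at E10 (97.4, 93.7, 96.7 and 97.3). Wnt feedback targets did at E8 (4.6) and at E10 (72.6), and kidney at E10 (97.3). The primitive streak list, with medians of -0.70 and 0.69, lay outside it at E10 only under other settings (97.9, 97.7, 98.6 and 98.6). At E8 it lay outside as reported (1.2) and inside with a pseudocount of 5 (5.2).

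The opposite ratios of presomitic mesoderm and heart genes were weighed first. Dilution of embryo RNA by other tissue would lower embryo genes at E8 by 1 factor, as far as that tissue does not express them. Of 24 members of both lists at 5 FPKM or more in wild type, 8 (1 of them listed at 0 in Tc/Tc) had log2 ratios of -3 or less. Another 9 lay above -1. This argues against dilution as the whole cause only if the other tissue does not express the 9, which was not examined. As a part of the cause it stays open. An earlier stage would put Tc/Tc E10 levels between those of wild type at E8 and E10. How many genes lie there depends on their fall in wild type, and the other higher genes were not matched on it. Setting the lists against them therefore does not test a lag. All 7 presomitic genes that were higher at E10 lay between these values in Tc/Tc, as under an earlier stage, against 45.4% of 619 other higher genes. Of the 4 higher heart genes 0 lay there and 4 lay above both wild-type values, by log2 ratios of 0.36 to 1.01 to wild type E8, all by more than the gene differed between 2 estimates of 1 library, against 54.6% of the other genes (37.5% by more than that), so with 4 genes a lag and a further effect cannot be told apart. No library earlier than E8 or between the stages was analysed here. For the E8 pattern a lag and a direct effect of the allele therefore both stay open. So does a difference in the age of the collected embryos, since the labels give this stage as E7.5 to 8.0.

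Visceral endoderm and yolk sac genes were higher in Tc/Tc at both stages. A larger share of 1 extraembryonic tissue would add its transcripts in a fixed proportion, if the tissue expressed them alike at both stages. The gain in FPKM at E10 over that at E8 lay within 2-fold of its median of 0.296 for 12 of 14 genes, from 0.165 to 1.11 in all. Many members were near 0 in wild type E10, such as Cubn at 0.249 FPKM, so their gain is nearly the Tc/Tc level. No other list was set beside this count, and any cause that moves the list together can give it. It therefore does not test a larger share. An earlier stage would put Tc/Tc E10 between wild type E10 and wild type E8. There lay 12 of the 14 genes estimated in both tables, against 45.4% of other genes higher at E10. From E8 to E10 the list had a median log2 ratio of -4.96 in wild type, so a wide range of gains lands between these values. The other genes were not matched on this fall. Setting the list against them therefore does not test an earlier stage. Both explanations therefore stay open, and they can hold together. Whether the yolk sac was removed to the same extent from each embryo is not given in the sources used here.

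Hypoxia and glycolysis genes were higher in Tc/Tc at E10. Lower re-estimated wild-type values in that table would end the pattern when the other wild-type estimate is used, but 9 of the 10 genes stayed past the rule, with a list median of 1.11. A lag with levels between those of wild type at E8 and E10 was not decided. All 10 genes lay above both wild-type values in Tc/Tc E10, against 54.6% of 619 other higher genes, though within 2-fold of wild type E8. Their log2 ratios to wild type E8 were 0.09 to 0.72, and 9 exceeded the median over all genes, 0.10. Above it by more than the gene differed between 2 estimates of 1 library lay 8, against 37.5% of the others. That margin leaves out the spread between embryos and library preparations. Passing the size rule also puts a gene above both values when its wild-type level fell less than 2-fold. From E8 to E10 the list had a median of -0.75 in wild type and of 0.57 in Tc/Tc, or 0.26 with the other estimate of Tc/Tc E8, and this decides nothing about a lag, since no stage before E8 or between the stages was sampled. A peak in wild type between the sampled stages, and a difference in oxygen supply or in handling, were not tested and stay open.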

How the results depend on the processing

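The counts changed with the settings, while no named gene past the size rule and no list median outside the middle 95% changed sign. Which direction held more genes also changed. At E8 the split was 368 higher and 546 lower with equal totals, and 358 and 419 with the other tables. At E10 it was 487 and 568 when centred, and for the wild-type stages 739 and 796 with the other tables. Chosen after seeing the data were adjusted p-values of the authors' deposited tables, protein-coding genes only, genes above 0 in both libraries only, the other tables for shared genes, lists and named genes, and each setting for genes in opposite directions. Counts are given as higher and lower. At E8 they were 858 and 702 with a pseudocount of 0.1, 205 and 102 with 5, 1470 and 1013 at a fold of 1.5, 83 and 71 at a fold of 4. There 204 were lower with a minimum of 5 FPKM, and 368 and 358 higher with equal totals and with the other tables. At E10 they were 272 and 147 with a pseudocount of 5, 2108 and 953 at 1.5-fold, 155 and 114 at 4-fold; 720 were lower with a pseudocount of 0.1, 242 with a minimum of 5 and 225 among protein-coding genes. For the wild-type stages they were 337 and 287 with a pseudocount of 5, 579 and 486 with a minimum of 5, 2309 and 1832 at 1.5-fold, 255 and 161 at 4-fold; 1586 were higher with a pseudocount of 0.1 and 672 among protein-coding genes. For the Tc/Tc stages they were 1694 and 848 with a pseudocount of 0.1, 326 and 217 with 5, 2648 and 1321 at 1.5-fold, 213 and 95 at 4-fold, and 644 were higher with a minimum of 5.

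Genes higher in both genotype comparisons numbered 79 with a pseudocount of 5, 126 with a minimum of 5, 550 at 1.5-fold and 110 with the other tables; genes lower in both 77 with a pseudocount of 0.1, 7 with 5, 19 with a minimum of 5 and 144 at 1.5-fold. Genes in opposite directions numbered 125 and 16 with pseudocounts of 0.1 and 5, 34 with a minimum of 5 and 228 at 1.5-fold. Lower folds, pseudocounts and minimums pass more genes by construction; the cause of the shifts with equal totals and other tables was not tested. The other 63 of 114 counts were within 1.5 times the reported one. Dropping the minimum changed no count, since the size rule already needs about 1 FPKM. Over 2091 values of named genes no gene past the size rule changed sign, and over 597 list medians none outside the middle 95% of random lists did; 836 and 199 of these values moved by more than 0.174, the SD between estimates of 1 library. Of 721 list percentiles, 19 moved into that middle and 7 out of it. The authors' calls of significance and their marks of tested genes were not run, as the table headers name neither. No paired analysis was possible because each group has 1 library. Depth is unknown, so a value listed at 0 sets no upper limit.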

Other observations

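Some gene groups outside the fixed lists stood out, and they were picked after their values were seen. Of 8 sarcomere and cardiac muscle genes outside the heart list, all 8 were lower at E8, and 4 were higher by the size rule at E10. Ttn, titin, was at 0.0113 FPKM in Tc/Tc and 5.81 in wild type at E8, and at 14.1 and 9.98 at E10. Mybpc3 and Csrp3 were listed at 0 in Tc/Tc at E8, against 6.30 and 5.69 FPKM, and had log2 ratios of 0.54 and 0.33 at E10. Myocd, a smooth and cardiac muscle coactivator, had log2 ratios of -2.13 at E8 and 1.72 at E10. Of 5 nuclear receptor and retinoid genes, 4 were lower at E8 and 1 at E10, while Rarb passed at neither stage (-0.77 and -0.27). The orphan nuclear receptor Nr2f1 was at 0.0772 against 9.98 FPKM at E8 and 46.0 against 105 at E10, and the retinoic acid binding protein gene Crabp1 at 24.5 against 115 and at 197 against 312.

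Of 6 lysosomal protease genes looked at, 5 were higher in Tc/Tc at both stages, among them 3 given here. Legumain (Lgmn) had log2 ratios of 1.64 at E8 and 1.97 at E10, Ctsl 1.12 and 1.65, and Ctsc 1.86 and 2.05. The exception was Dpp7, with 1.57 at E8 and -0.07 at E10. The metallothioneins Mt1 and Mt2 had ratios of 2.08 and 2.94 at E8 and of 1.08 and 0.87 at E10. Of 6 X-linked genes, also picked after their values were seen, all 6 were higher at E8. At E10 4 were higher, and Xlr4a and Mageb16 were below 1 FPKM in both libraries and not measured. The share over all X-linked genes was not computed. Trap1a was at 61.4 against 21.3 FPKM at E8 and at 9.92 in Tc/Tc at E10, where wild type was listed at 0, and Nxf7 at 73.5 against 18.9 and 12.1 against 0.437. Within each stage the 2 libraries were alike in Xist and Y-linked genes.

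A hypothesis formed from these values is that much of the E10 difference reflects a lag of the Tc/Tc embryos behind wild type. Its test, and the bound of 75% used in it, were chosen after the values were seen. The mean of the wild-type and Tc/Tc stage ratios served as a stage axis, since under equal noise it shares no net error with the genotype ratio. Of 849 genes past the size rule at E10 and outside the visceral endoderm and yolk sac list, 77.7% lay on the E8 side, which is consistent with a lag; the share was 86.4% of the lower genes and 74.3% of the higher ones, the latter under the bound. Of 619 genes higher at E10 outside the lists weighed above, 54.6% lay above both wild-type values and 45.4% between them. Only 37.5% lay above both and exceeded wild type E8 by more than the spread between estimates. Within 2-fold of wild type E8 lay 82.2%. The size rule itself puts a gene above both values when its wild-type level fell less than 2-fold. This split therefore does not decide for or against a lag. Of 802 genes past the size rule at E8 and outside the visceral endoderm and yolk sac list, 80.0% lay on the E8 side. A gene that differs in Tc/Tc E8 alone falls there by construction, so this share does not test a lag. Leaving out the visceral endoderm and yolk sac list, Tc/Tc E10 differed by the size rule from wild type E8 in 483 of 14229 genes. It differed from wild type E10 in 945 of them with the estimate of the wild-type stage table, which also gave wild type E8, and in 1072 with that of the E10 genotype table. The wild-type stage table is not the one that gave Tc/Tc E10, and wild type E8 differs from both in sex-linked genes. A departure of wild type E10 alone would also give the larger counts against it. A difference in the age of the collected embryos that is unrelated to genotype would give the same values.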
